A study of Homo sapiens with 6 samples.

How the data were processed

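RNA was measured in HEK293 cells, an established human embryonic kidney line, after silencing of PUM1 and PUM2 and after a non-targeting control. Per the labels' protocols, cells received pooled siRNAs in repeated transfections and were harvested 48 hours after the last one. Another label calls the reagent an shRNA, and the labels do not settle the difference. Poly(A) RNA was purified and libraries were made with a TruSeq RNA kit, per the labels' protocols. Whether the libraries kept strand is not given in the sources used here. The 6 samples form 2 groups of 3, and nothing in the labels names a batch.

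The deposited values are FPKM, sequenced fragments scaled to transcript length and to the size of the library, per the file headers. Each group has 1 FPKM value per gene for its 3 samples together, so the authors' values carry no spread between samples. The submitters' processing notes name CASAVA, TopHat2 2.0.9, Bowtie2 2.1.0, Cufflinks 2.1.0, Cuffdiff 2.1.1 and the hg19 build, without their settings. A repeated header line inside each table carries the names Cuffdiff gives the values of its conditions, and this 1 line was left out. Read counts and depth are unknown. Low values were searched for steps of whole reads. Among 2833 symbols above 0 in both groups and under 0.2 FPKM in the control, the most common ratio of the 2 values, to 3 decimals, was held by 11 symbols (0.388%), so whole reads were not recoverable.

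Each table held 19219 rows and 19135 symbols. The 79 symbols on more than 1 row, 29 of them among the tested genes, were summed, because such rows could not be paired between the groups. No symbol was at 0 in both groups, 466 were listed at 0 in the control and 552 in the knockdown. Genes with a mean of at least 1 FPKM over both groups entered the comparisons (13341 symbols, called tested genes below although no statistical test was run). Of these, 358 shared both values with at least 1 other symbol, as overlapping or nested genes can, and up to 22 symbols shared 1 pair of values. Folds are on the scale of log2(FPKM + 1), knockdown minus control, which understates the difference of low genes. Because there is 1 value per group, no statistical test was possible and no p-value is given. Genes were counted by size, at 1.5 times or more on that scale.

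Before the data were examined, 26 lists with 560 entries were fixed, of which 542 were matched to symbols in the tables. The median log2 fold of a list was placed among the medians of 10000 random lists of the same size matched on mean expression in 10 bins. A list is called above or below the random range when its percentile lies over 97.5 or under 2.5. These percentiles describe the pooled values and are not tests across replicates.

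The search for Pumilio response elements used the longest annotated 3' UTR per protein-coding gene in GENCODE 29, which is on another build than the authors' values. Genes were joined by symbol alone and no coordinates are given. In all, 17190 symbols were matched, 15762 by the GENCODE symbol, 25 by another current symbol and 1403 by a RefSeq synonym. Of the tested genes, 12445 had a 3' UTR of at least 8 nt and 896 (6.72%) had none. The element was UGUANAUA and the control motif was its reversed order, AUANAUGU. Random lists for the element were matched on mean expression and 3' UTR length, in 10 bins each. All 7-mers present in at least 50 3' UTRs were also scored. The score compared genes with and without the 7-mer, after a linear fit of the log2 fold, limited to 1 in either direction, on expression, 3' UTR length and AU share. PUM1 and PUM2 were left out of that scan, and the range of chance came from 100 shufflings of the genes.

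The rule for named genes was fixed before the data were examined. It takes PUM1, PUM2 and PUM3, and the 12 highest and 12 lowest folds among genes with at least 5 FPKM in the higher group. From each list it takes the highest and the lowest member and up to 2 more by size, with a mean of at least 1 FPKM, and it allows all such members of the lists of Pumilio genes, partners and literature targets. It also takes the 5 highest and 5 lowest folds among genes with 2 or more elements and at least 5 FPKM in the higher group. Because small-RNA genes filled most of the rule's extremes, the extremes without them are given as well, a choice made after the values were seen.

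The alternatives fixed before the data were seen were a pseudocount of 0.1, centring of the median fold, no filter or a mean of at least 5 FPKM, symbols on several rows left out, thresholds of 2 times and of 25% above the other group, random lists without matching, and other definitions and locations of the element. Alternatives chosen after seeing the data left out small-RNA genes, repeated values, genes with the element, PUM1 and PUM2, or genes with certain 7-mers, and added matching on 3' UTR AU share. The calculations were tested on simulated data. Of 100 lists of 25 genes with no shift, 2 lay above the random range and 0 below. With a planted shift of 0.1 on the log2 scale 67 lay above, and with 0.2 all 100 did. The simulated lists held random genes with shuffled folds, and do not show how often lists of genes that vary together leave the range. A 7-mer planted with a shift of -0.05 was ranked lowest in 19 of 20 runs, and with -0.1 in 20 of 20. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.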

Results

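Expression was compared between HEK293 cells depleted of PUM1 and PUM2 and cells given a non-targeting control, to find RNAs regulated by the human Pumilio proteins. These proteins bind RNA through the sequence UGUANAUA, the Pumilio response element, and are known mainly as repressors of the mRNAs they bind. Each group comprised 3 samples, which the deposited tables combine into 1 FPKM value per gene. There are therefore no replicate values, and no value below has an error or a test across samples. The depth of the libraries is unknown. The values summed to 380227 FPKM in the control and 375482 in the knockdown, with medians of 6.23 and 6.29 FPKM over all symbols.

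Both targeted transcripts were lower in the knockdown. PUM1 had 36.4 FPKM in the control and 14.1 in the knockdown, 0.386 times the control value (log2 fold -1.31). PUM2 had 26.0 and 7.45 FPKM, 0.287 times the control (log2 fold -1.68). PUM3, listed as KIAA0020, is a distant relative that was not targeted and had 29.5 and 28.9 FPKM. Among Pumilio partners, NORAD, a long noncoding RNA rich in Pumilio binding sites and listed as LOC647979, had 59.5 FPKM in the control and 75.8 in the knockdown. NANOS1, whose protein family acts with Pumilio proteins, had 4.64 and 5.28 FPKM.

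Most transcripts differed little between the groups. Of 13341 tested genes, 165 were higher in the knockdown by at least 1.5 times and 85 were lower. Counts and shares by size of fold, here and below, use FPKM + 1, so genes past 1.5 times in plain FPKM can fall short. The median log2 fold was -0.01, the middle 50% of genes lay between -0.12 and 0.11, and in 90.3% of genes the higher group exceeded the lower by less than 25%. The counts depended on low values, being 269 higher and 141 lower with a pseudocount of 0.1, while 55 genes were lower once small-RNA genes were left out.

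Among genes other than small-RNA genes, an exclusion chosen after the values were seen, GOLIM4, a Golgi membrane protein, had the highest fold, with 55.0 FPKM in the control and 139 in the knockdown. DNASE1L2 had 4.58 and 11.7 FPKM, SMPDL3A had 5.60 and 13.9, and the Wnt receptor gene FZD8 had 7.80 and 18.6. VLDLR, a lipoprotein and reelin receptor, had 22.2 FPKM in the control and 2.25 times that in the knockdown. CCDC12 had 18.7 and 41.9 FPKM, and the nuclear receptor coactivator PNRC1 33.2 and 70.8. ERLEC1, a lectin of the endoplasmic reticulum, had 2.21 times its control value. The other genes among the 12 highest were ALDH1A3, a retinaldehyde dehydrogenase, PLAT, the tissue plasminogen activator, CPXM1 and the kinase gene MAP4K3, at 2.05 to 2.20 times the control. Of these 12 genes, 8 held UGUANAUA in the 3' UTR.

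The lowest folds outside small-RNA genes were also ranked among genes with at least 5 FPKM in the higher group. The 12 lowest included PUM2 and PUM1, the 2 of them with an element in an annotated 3' UTR. AKR7A2, an aldo-keto reductase, had 32.4 FPKM in the control and 10.5 in the knockdown, and TAGLN, an actin-binding protein, had 18.0 and 6.29. EDEM2, which acts in degradation of misfolded glycoproteins, had 8.72 and 3.42 FPKM, and ANKRD54 had 39.1 and 17.3. ELAVL1, the RNA-binding protein HuR, had 13.9 FPKM in the knockdown, 0.463 times the control. INSIG1, which restrains cholesterol synthesis, had 132 and 69.2 FPKM. CHPT1, SLC25A15 and the pseudogenes AKR7A2P1 and TTC3P1 were at 0.402 to 0.503 times the control. The 3' UTRs of AKR7A2, ELAVL1 and INSIG1 hold the 7-mer GAGCGCU, which went with lower values across genes. The values of AKR7A2 and AKR7A2P1, and of TTC3 and TTC3P1, are uncertain, since reads from a gene and its pseudogene can be assigned to either.

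Small-RNA genes, such as those of microRNAs and small nucleolar RNAs, filled 11 of the 12 highest and 7 of the 12 lowest places under the fixed rule. Of 122 such genes tested, 33 were higher and 30 lower by at least 1.5 times, 51.6% of them against 1.41% of other genes. MIR940 was listed at 0 in the control and 42.5 FPKM in the knockdown, and MIR33B at 0 and 32.6. SNORD83B was listed at 42.3 FPKM in the control and 0 in the knockdown, and MIR3944 at 10.6 and 0. Of 29 tested symbols listed at 0 in 1 group, 28 were small-RNA genes. FPKM of genes this short rests on little sequence, and no fold is given against a value of 0. The libraries were made from poly(A)-purified RNA, so these values need not measure the mature small RNAs.

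**Figure D1:**
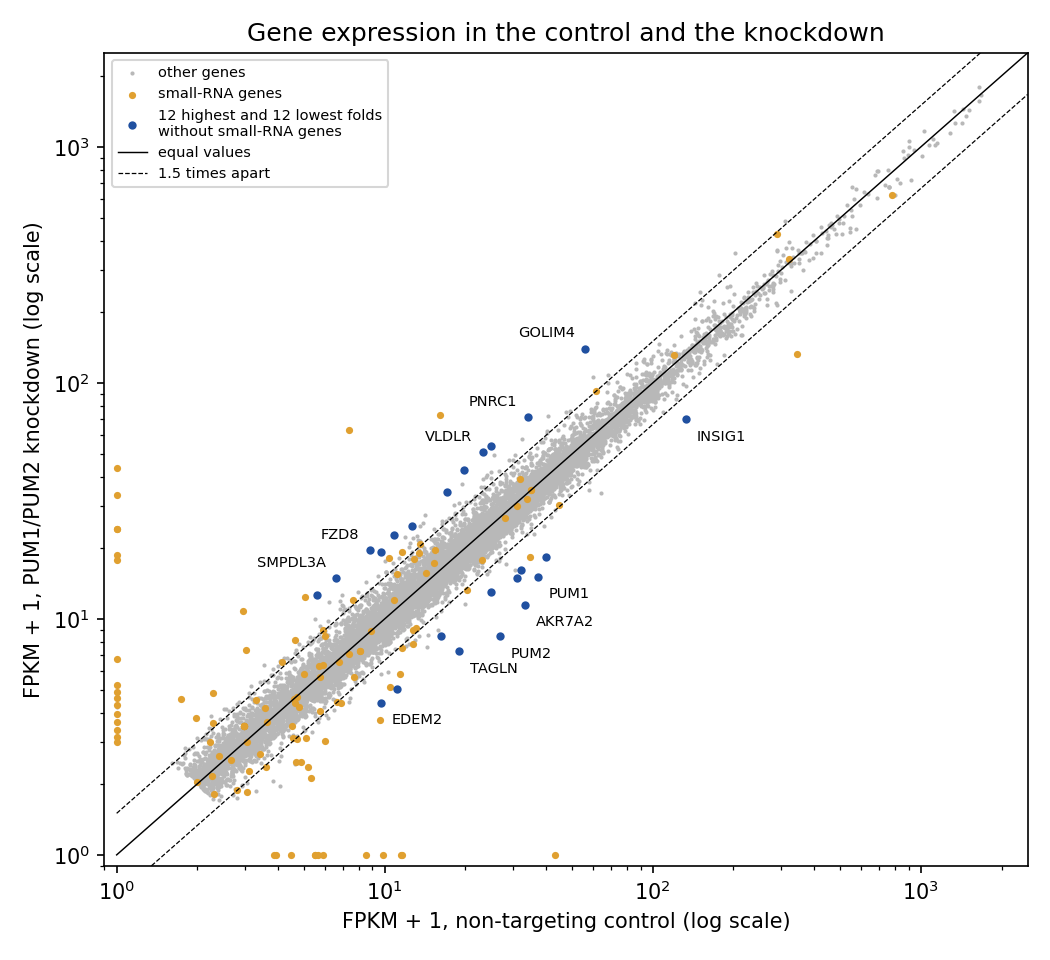
FPKM + 1 of each tested gene in the control (x axis) and the knockdown (y axis), both on log scales, 1 point per gene. Small-RNA genes are orange, and blue points are the 12 highest and 12 lowest folds among other genes with at least 5 FPKM in the higher group. The solid line marks equal values and the dashed lines 1.5 times. PUM1 and PUM2 lie below the lower dashed line, and GOLIM4 lies above the upper one at 55.0 and 139 FPKM.

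Transcripts with a Pumilio response element in the 3' UTR were higher in the knockdown than transcripts without one. Of 12445 tested genes with an annotated 3' UTR, 3779 (30.4%) held UGUANAUA. Their median log2 fold was 0.04, against -0.03 for the 8666 genes without it, a difference of 0.069. Among 10000 random lists matched on expression and 3' UTR length, the median of genes with the element was at percentile 100, and the middle 95% of the random medians ran from -0.00796 to 0.000387. Of 125 genes with a 3' UTR that were higher by at least 1.5 times, 82 (65.6%) held the element, as did 14 (28.6%) of 49 that were lower. Both the 14 and the 49 include the silenced genes PUM1 and PUM2. With no filter on low values the difference was 0.0349.

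The fold was higher with more elements. The median log2 fold was 0.02 for 2411 genes with 1 element, 0.08 for 891 genes with 2 and 0.09 for 477 genes with 3 or more, each at percentile 100. The share of genes higher by at least 1.5 times was 0.496% with 0 elements, 1.33% with 1, 3.03% with 2 and 4.82% with 3 or more. Genes with 2 or more elements and at least 5 FPKM in the higher group were ranked by fold. The highest folds were those of SMPDL3A (2 elements), VLDLR (3), CCDC12 (3), PNRC1 (2) and MAP4K3 (4). The lowest were those of PUM2 itself, SERTAD2 with 14.8 and 7.95 FPKM, C20orf177 with 8.70 and 4.86, the corepressor gene LCOR with 7.31 and 4.57, and RASEF with 25.1 and 16.7. SERTAD2 and C20orf177 also hold the 7-mer GAGCGCU.

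**Figure D2:**
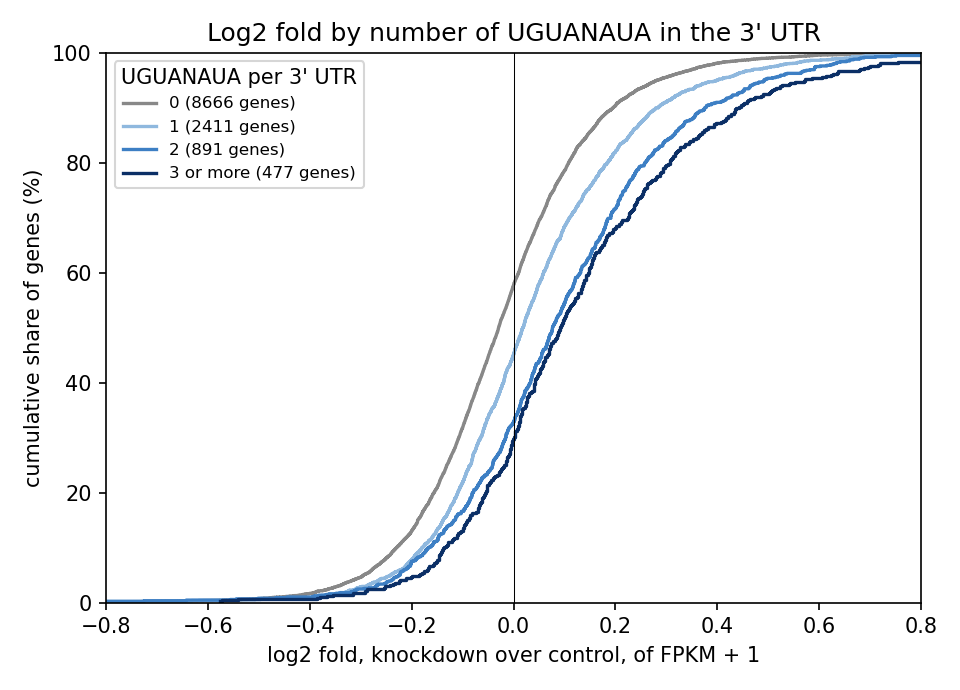
Cumulative share of tested genes (y axis, %) by log2 fold of FPKM + 1, knockdown over control (x axis), with 1 line for each number of UGUANAUA in the 3' UTR. Folds outside the plotted range are not drawn. The lines shift to the right with more elements, with medians of -0.03 for 0 elements, 0.02 for 1, 0.08 for 2 and 0.09 for 3 or more.

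The control motif AUANAUGU also went with higher values, by a smaller difference. Its 3162 genes had a median log2 fold of 0.01, at percentile 100, and differed from genes without it by 0.0296. Its median also rose with number, from 0.0047 with 1 to 0.0208 with 2 and 0.0503 with 3 or more (percentiles 99.28, 99.93 and 100). The share of genes higher by at least 1.5 times was 1.38% with 1 control motif, close to that with 1 UGUANAUA, 1.55% with 2 and 0.578% with 3 or more, the last being 2 of 346 genes. With UGUANAUA in the coding sequence, 659 genes had a median of 0.04, at percentile 100. With the element in the 5' UTR, 151 genes had a median of -0.0044 at percentile 66.9, inside the random range. In both cases matching used the length of the region searched. Genes that also hold UGUANAUA in the 3' UTR were left out neither there nor for the control motif.

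Of the lists fixed beforehand, 7 had medians above the random range. The 18 genes described in the literature as Pumilio targets had a median log2 fold of 0.10 (percentile 99.7), with 2 members higher by at least 1.5 times and 1 lower. The 2 were FZD8 and PCNA, the sliding clamp of DNA replication, at 311 and 485 FPKM, and the 1 was the MAP kinase phosphatase DUSP6, at 3.09 and 1.62 FPKM. The cyclin-dependent kinase subunit CKS2 had 151 and 224 FPKM and the cell cycle inhibitor CDKN1B 38.0 and 42.1, while E2F1, PTEN and ATXN1 had 0.997, 0.983 and 0.966 times their control values.

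Wnt signalling genes had a median log2 fold of 0.13 (percentile 99.99, 30 genes), with 22 above 0 and 3 higher by at least 1.5 times. Besides FZD8, these were the R-spondin receptors LGR5, with 12.9 and 24.4 FPKM, and LGR4, with 19.0 and 30.2. TCF7L1 had the lowest fold of this list, with 9.14 and 7.62 FPKM. Mitosis and chromosome segregation genes had a median of 0.09 (percentile 99.99, 31 genes), with 21 above 0 and 0 past 1.5 times. The kinase genes CDK1 and TTK had 1.36 and 1.34 times the control value, and the cohesin subunit RAD21 had 1.32 times. The condensin subunit NCAPG had 0.859 times.

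Targets of p53 had a median log2 fold of 0.10 (percentile 99.6), with 18 of 20 above 0 and 0 past 1.5 times. BTG2, an antiproliferative factor, had 37.3 and 55.0 FPKM, the proapoptotic gene BBC3 23.6 and 34.6, and RRM2B, a ribonucleotide reductase subunit, 13.0 and 18.3. Histone genes had a median of 0.15 (percentile 99.95, 17 genes), with 1 higher by at least 1.5 times, the linker histone HIST1H1C at 39.8 and 71.7 FPKM. The variant histone H2AFY had 183 and 131 FPKM. Transcripts of replication-dependent histones mostly lack poly(A) tails, so poly(A)-purified RNA samples them in part.

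Extracellular matrix and adhesion genes had a median log2 fold of 0.06 (percentile 98.2, 23 genes), with 1 higher by at least 1.5 times, the adhesion molecule L1CAM at 2.85 and 5.16 FPKM. The integrin gene ITGAV had 38.5 and 57.6 FPKM. Apoptosis genes had a median of 0.07 (percentile 97.8, 23 genes) with 0 past 1.5 times, and BCL2L11, a proapoptotic gene with 5 elements, had 16.8 and 23.1 FPKM. Without genes that hold UGUANAUA, a choice made after the values were seen, the mitosis, Wnt, matrix and apoptosis lists lay inside the random range, at percentiles 62.8, 35.5, 90.7 and 94.2. Each of these lists then held fewer genes, which widens the random range, so a list can come to lie inside it by size alone. The literature list then held only 2 genes, MAPK1 and E2F1, too few to place. The matrix and apoptosis lists also lay inside it with unmatched random lists, at percentiles 94.3 and 96.9.

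Interferon response genes were lower as a list, with a median log2 fold of -0.30 (percentile 0) and 15 of 19 expressed members below 0. IFIT3 had 6.35 FPKM in the control and 3.44 in the knockdown, and IFI6 35.2 and 22.0. These 2 were lower by at least 1.5 times on the scale of FPKM + 1. IFIT1 had 11.1 and 7.22 FPKM, 0.652 times the control, but with a log2 fold of -0.554 it fell short on that scale. STAT2, a transcription factor of the interferon pathway, had 18.4 and 21.4 FPKM. The groups differed in the silencing reagent delivered as well as in PUM1 and PUM2. The only other list below the random range was that of the 3 Pumilio genes (median -1.31, percentile 0), which holds both targets.

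Lists inside the random range held single genes with larger differences. Genes of G1/S transition and replication had a median log2 fold of -0.10 (percentile 3.65), with 20 of 26 members below 0. Against that direction, PCNA and SLBP, the histone stem-loop binding protein, were higher by at least 1.5 times, SLBP at 48.2 and 74.9 FPKM, and cyclin CCNE2 had 8.11 and 12.2. GINS2, a replication factor, had 56.6 and 43.9 FPKM. This list lay below the range with unmatched random lists, at percentile 1.09. MAP kinase feedback and early genes had a median of -0.07 (percentile 5.39, 28 genes), with 3 lower by at least 1.5 times. These were DUSP6 and the transcription factors ETV4, at 3.08 and 0.950 FPKM, and ETV5, at 2.31 and 0.873.

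The machinery of deadenylation and decapping had a median log2 fold of -0.03 (percentile 46.0, 29 genes) and a mean of 0.02, with BTG1 at 14.1 and 20.5 FPKM and the deadenylase gene CNOT8 at 26.4 and 36.7. RNA interference genes had a median of -0.03 (percentile 34.0), with EIF2C2 at 1.17 times the control. Unfolded protein response genes were at percentile 74.1, heat shock genes at 65.8, TGF-beta and BMP genes at 58.8 and chromatin and Polycomb genes at 45.9. In the heat shock list the chaperonin HSPE1 was higher by at least 1.5 times, with 46.3 and 74.0 FPKM. Median and mean differed in sign for the deadenylation, RNA interference, unfolded protein, heat shock, TGF-beta and other-cell lists.

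Cholesterol synthesis genes had a median log2 fold of -0.05 (percentile 36.5, 20 genes), with INSIG1 lower by at least 1.5 times and SQLE, which makes squalene epoxide, at 41.1 and 53.9 FPKM. Hypoxia and glycolysis genes were at percentile 34.2, with PKM2 at 802 and 621 FPKM. Nuclear genes of oxidative phosphorylation were at percentile 80.5, ribosomal protein genes at 96.9, neuronal genes at 90.3 and housekeeping genes at 52.1. Of the neuronal list, ELAVL2 had 9.91 and 15.2 FPKM and NEFM, a neurofilament subunit, 45.7 and 34.9. Of markers of other cell types, 8 of 22 were expressed, with a median log2 fold of -0.06 inside the random range, and the keratin gene KRT17 had 288 and 214 FPKM. HBA1, at 0.867 and 1.80 FPKM, was the 1 member higher by at least 1.5 times. The 2 expressed genes of the partner list were at percentile 95.9, and of 15 mitochondrially encoded genes 0 were matched in the tables used here.

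**Figure D3:**
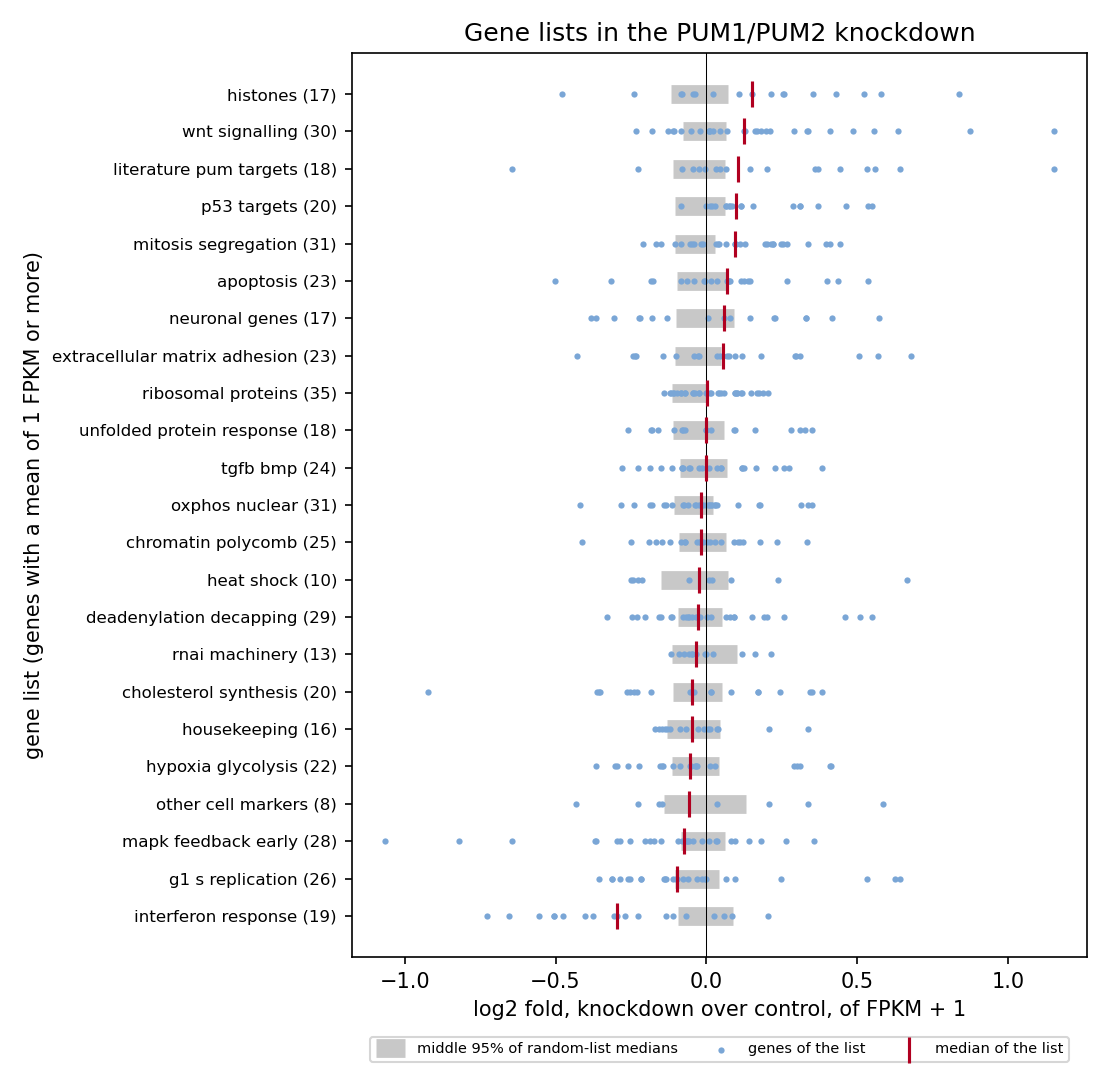
Log2 fold of FPKM + 1, knockdown over control (x axis), for each fixed list (y axis, expressed genes in brackets), with points for genes and red bars for medians. Grey bars span the middle 95% of medians of 10000 random lists matched on expression. The Pumilio gene and partner lists are not drawn. The interferon median of -0.30 lies to the left of its grey bar, and the histone median of 0.15 and Wnt median of 0.13 lie to the right of theirs.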

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

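No paired analysis was possible because each group has 1 pooled value per gene. For the same reason, leaving out each replicate and the replicate block were not run, and neither was the planned count model, since there are no counts. The limit set by depth is unknown. Settings that left out small-RNA genes, repeated values, genes with the element, genes with GAGCGCU or GGAGAUA, or PUM1 and PUM2, and matching on AU share, were chosen after seeing the data.

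The element difference of 0.069 was positive in all settings run, from 0.00567 to 0.0775. It was 0.00567, inside the random range, with the element in the 5' UTR. PUM1 and PUM2 were lower in both settings run. Gene counts moved with the threshold by construction, to 34 higher and 26 lower at 2 times and 788 and 504 at 25% above the other group. They were 269 and 141 with a pseudocount of 0.1. Lower genes numbered 50 at a mean of at least 5 FPKM and 55 without small-RNA genes, where fewer genes were tested. Lists above the random range numbered 3 without genes that hold UGUANAUA. There, cholesterol synthesis (-0.23, percentile 0) and neuronal genes (-0.16, percentile 0.93) lay below the range and ribosomal proteins above it (percentile 99.5), and the cause was not tested. Of values of named genes under the alternatives, 285 stayed on their side of 1.5 times and 5 passed it. Of list medians, 204 kept their side of the range, 8 lost it and 4 passed it. None reversed.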

Other observations

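Apart from UGUAHAUA, which was planned, the tests in this part were chosen after the data were seen, namely the scan and the tests of GAGCGCU and GGAGAUA picked from it, matching on AU share, the arrangements, genes with 2 or more elements, the interferon list without its 2 lowest members, the genes of RNA sensing, and the split of the mitosis and Wnt lists by the element.

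A scan of all 7-mers in 3' UTRs, with no motif given, ranked parts of the Pumilio response element highest. Of 16244 7-mers scored over 12443 genes, 29 scored above the highest shuffled score of 4.62, and 6 of these are part of UGUANAUA. The highest were UGUAAAU (score 11.9), GUAAAUA (11.2), UGUAUAU (10.9) and GUAUAUA (10.3). At the other end, 3 7-mers scored below the lowest shuffled score of -4.86, namely GAGCGCU (-7.83), GGAGAUA (-5.98) and AGGAGAU (-5.71).

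The higher values of transcripts with UGUANAUA were weighed against base composition. Random lists matched on expression, 3' UTR length and AU share had medians of -0.000257 to 0.00898 (middle 95%), and the observed median stayed at percentile 100, which argues against length and AU content as the whole cause. Only 1 of 140 arrangements of the same bases, UGUANAUA itself, gave a shift as large (0.06), and the next, UAUANGUA, gave 0.03. These shifts are mean differences after the fit used for the scan. Without G at the variable position (UGUAHAUA) the difference of medians was 0.0716, against 0.069 for UGUANAUA. Among genes with an element, the 1368 with 2 or more had a median of 0.08, at percentile 100 of length-matched lists, so loss of repression that grows with the number of elements is a candidate explanation. The median of the control motif also rose with number, to 0.0503 with 3 or more. Genes that also hold UGUANAUA were not left out there, so whether a rise with number is particular to the element was not settled. Indirect effects of the knockdown, and how the samples varied, remain open.

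The lower interferon list was weighed in the same way. Matched on expression, 3' UTR length and AU share it stayed at percentile 0, so composition does not account for it. Without its 2 lowest members the median was -0.27, also at percentile 0. A median moves little when 2 members are left out, but 15 of 19 members lay below 0, so the shift was not limited to 1 or 2 genes. A different response to the control and targeting reagents may be the cause, and it cannot be told apart from loss of PUM1 and PUM2, because each reagent marks 1 group. How the samples of each group varied is unknown, so variation between samples remains open as well. The 5 expressed genes of RNA sensing, among them DDX58 and EIF2AK2, had a median log2 fold of -0.13 (-0.1348), but all are members of this list, so that value does not decide between the causes.

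Lower values of genes with GAGCGCU may reflect off-target pairing of the seeds of the silencing reagent. GAGCGCU, in 303 genes, scored -7.83, and of these genes 20 were lower and 2 higher by at least 1.5 times. The lower ones included AKR7A2, ELAVL1, INSIG1 and TTC3. Of 1139 genes with GGAGAUA, 6 were lower and 11 higher by that much, against 47 lower and 125 higher of all 12443 scanned genes. A shortage of UGUANAUA does not account for GAGCGCU as a whole. Of its 303 genes, 205 lacked UGUANAUA, against 8666 of 12445 tested genes with a 3' UTR. The mean difference of GAGCGCU was -0.0645 among genes without the element and -0.0875 among all, and GGAGAUA was not tested in this way. As a hypothesis on the source, 1 of 2 extended octamers lies in a target, UGAGCGCU in 8 of 11 PUM2 transcripts (3.96% of genes within 25% of its length hold it) and AGGAGAUA in 0 of either gene, and without the sequences of the reagent, not used here, a seed cannot be told apart from other causes.

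The mitosis and Wnt lists may lie above the random range through their members with UGUANAUA. In the mitosis list, 18 members with the element had a median log2 fold of 0.16 and 13 without it -0.04, at percentile 65.3 of random genes without the element. In the Wnt list, 19 members with it had a median of 0.17 and 11 without it -0.05, at percentile 33.5. In both lists the median of the members with the element lay above 0.04, the median of all 3779 genes with it. These members were not placed among random genes with the element, so whether the element alone accounts for them remains open.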
